A study of Mus musculus with 4 samples.

How the data were processed

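Haematopoietic stem cells (HSC) sorted from mouse bone marrow were profiled by single-cell RNA sequencing in 4 libraries, 2 from Mat KO animals and 2 from wild-type (WT) animals. Per the labels' protocols, single cells were picked by mouth pipette into lysis buffer and processed with a modified STRT-seq method. In this method an oligo-dT primer carries a cell barcode and a unique molecular identifier (UMI), so each count stands for a tagged cDNA near the 3' end of a polyadenylated RNA. Sequencing was paired-end on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.12, HTSeq and the mm10 build, without saying which step each did, and the gene names are those of refGene. The deposited values are raw UMI counts per gene and cell barcode, with no normalization and no filter on cells. How reads of multi-copy genes were assigned is not given in the sources used here.

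Each table held 24506 rows, of which 24411 were gene symbols and 95 were spike-in or marker sequences, 92 of these ERCC spike-ins. Spike-in rows stayed out of library sizes and tests. A total of 27 symbols had been turned into dates, as spreadsheet programs do, and were left as they stood. Each library had 96 barcodes, and only the first 48 held cells. Barcodes with at least 1000 detected genes were kept, which left 44 and 48 cells in Mat KO replicates 1 and 2 and 48 in each WT replicate, 188 in all. Cell numbers stated by the study were not used here. No doublet caller was run because cells were picked singly, and no cell lay more than 3 median absolute deviations above its library's median log UMIs.

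The kept cells held 1900319 and 1768647 UMIs in Mat KO replicates 1 and 2, and 3183279 and 3253608 in WT replicates 1 and 2. Within a library, cells ranged from 2229 to 160595, 2904 to 163777, 3759 to 287142 and 4188 to 223278 UMIs in that order. UMIs over-counted molecules. Spike-in species seen in at most 20% of wells gave a mean of 5.18 to 7.37 UMIs per well in which they were seen, where single molecules would give 1.05 to 1.08. Exact binomial 95% intervals, and the limit of 3 counts that a count of 0 allows, therefore cover counting error only and are too narrow for UMIs. Where shares of cells or genes per cell were compared, each cell was thinned to 8800 UMIs, the 10th percentile of the kept cells, which kept 170 cells and left out 18.

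Cells are not replicates, so counts of the kept cells were summed per library and the 4 sums were compared. The labels do not say whether the libraries of a genotype came from separate animals. Each library held cells with Xist and cells with Y-linked transcripts, so each pooled cells of at least 1 female and 1 male. P-values measure only the spread between these libraries, which may be technical. The column names of all 4 libraries carry the same flow cell and lane. Log2 CPM of the replicates correlated with a Pearson coefficient of 0.808 in Mat KO and 0.846 in WT.

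The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr and genotype as the only term, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are Mat KO minus WT, and standard errors are the fold change divided by the square root of its F statistic. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over all lists with at least 3 tested members. Camera was repeated with a correlation estimated per list and on ranks, and fry was run beside it. With an estimated correlation camera rests on the few residual degrees of freedom of 4 libraries, so few lists could pass after adjustment. Library medians and shares were compared by an exact two-sided permutation test, which cannot go below p = 0.333 with 2 libraries against 2. Clusters used scanpy 1.11.5 with 2000 variable genes, 20 components, 15 neighbours and Leiden resolution 0.5, leaving out locus and sex-linked genes.

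The test, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. Named genes were the detected locus genes with at least 10 UMIs, the genes of smallest p in each direction (up to 12 that pass, or 6 if fewer pass), the 4 leading members of each list that passed, and the 3 leading members of the stem cell, snoRNP, PI3K-mTOR, quiescence and G2/M lists. One gene named by this rule is not reported here. The lists covered the maternal, paternal and flanking genes of the locus, other imprinted genes, ribosomal proteins, ribosome biogenesis, snoRNPs, translation factors, tRNA synthetases, PI3K-mTOR, oxidative phosphorylation, mitochondria-encoded genes, glycolysis, the proteasome, cell cycle, stress and interferon programmes, and markers of blood and stromal cell types. Only 1 of 7 maternal and 1 of 3 paternal genes in the counts was tested, and the files used here hold no mitochondria-encoded gene, so these 3 lists were not tested as lists in the main fit. The maternal list had enough members in 3 alternatives and did not pass: it pointed up without a filter and without Mat KO replicate 1 (adjusted p = 0.825 and 0.726) and down without WT replicate 2 (0.265).

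A second set of sums was chosen after the data were seen. It holds 150 lineage-low cells and leaves out 38 cells of other lineages, those with at least 2% of their UMIs in granulocyte and monocyte markers, 0.25% in B-lymphoid markers, 0.15% in T and NK markers or 0.5% in erythroid markers. A total of 15 cells lay within 1.5-fold of one of these limits, so the class is a range and not a cell type. Lower and higher limits, each by 1.5-fold, were run as well. A cell over several limits got 1 class, in the order granulocyte and monocyte, B-lymphoid, T and NK, erythroid. This left 0 cells in the T and NK class, so B-lymphoid marker cells can also exceed the T and NK limit. The leading Mat KO cells of the T and NK marker Ccl5 were classed as B-lymphoid. The B-lymphoid list includes Cd74, H2-Aa and H2-Ab1, which other antigen-presenting cells also make. Cells were called Xist-positive or Y-positive from at least 5 UMIs of one kind and 5 times the other.

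Alternatives tried were RLE factors, totals without factors, other filters on genes and cells, DESeq2 1.42.0, thinned cells, a replicate block and each library left out. Those added after the data were seen were the lineage-low cells at 3 sets of limits, each gene's highest cell left out, cells with Xist, cells with Y-linked transcripts and counts without Rn45s. The procedure was tested on simulated data for Mat KO against WT over 10663 genes with 200 changed. It recovered 33.67% of 4-fold and 78.33% of 16-fold changes over 3 simulations, none with the wrong sign, and 6.667% of calls were false. A 40-gene list shifted 1.5-fold was found in 3 of 3 simulations with the preset correlation and in 2 of 3 with an estimated one. Genes were drawn independently there, and a list counted as found at an unadjusted p under 0.05. The real lists were judged on adjusted p and can hold correlated members (0.553 estimated for cytosolic ribosomal proteins), so the simulation does not test such lists.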

Results

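The Dlk1-Gtl2 locus is an imprinted region on mouse chromosome 12 whose maternal copy makes the noncoding RNAs Meg3 (also called Gtl2), Rian and Mirg, with many small nucleolar RNAs (snoRNAs) inside them, while the paternal copy makes Dlk1, Rtl1 and Dio3. The study's title concerns these snoRNAs in the self-renewal of long-term HSC through rRNA modification and translation. Single HSC from bone marrow of Mat KO animals (2 libraries, 44 and 48 cells) were set against HSC from WT animals (2 libraries, 48 cells each). Median depth per cell was 33612.5 and 27845 UMIs in Mat KO replicates 1 and 2, against 53092.5 and 51437 in WT replicates 1 and 2. Median spike-in UMIs per cell were lower in Mat KO as well, at 42788.5 and 43384.5 against 55772.5 and 48068.5. The lower depth is therefore not a measure of RNA content alone. Median genes per cell were 3369.5 and 3066 against 3761 and 4085.5, and at equal depth 2262 and 2293 against 2383.5 and 2516. In each of these the genotypes did not overlap (exact permutation p = 0.333, the smallest that 2 libraries against 2 can give).

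The first question was whether transcripts of the targeted locus differed. Meg3 (chromosome 12, 109541001 to 109571726, plus strand, a long intergenic noncoding RNA in mm10) was detected in all 4 libraries, with 35 and 58 UMIs in Mat KO and 168 and 153 in WT, or 18.4 and 32.8 against 52.8 and 47.0 CPM (UMIs scaled to the library total). Its log2 fold change of -0.93 (SE 0.55, n = 2 libraries each) did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.729), although the libraries of the genotypes did not overlap. Meg3 UMIs were present in 8 of 44 and 10 of 48 Mat KO cells and in 19 of 48 and 15 of 48 WT cells; at equal depth the shares were 12.8% and 19.5% against 19.6% and 13.6%, which overlap. Rian had 25 UMIs in 1 cell of Mat KO replicate 2 and 0 elsewhere. Mirg had 47 UMIs in 3 cells of WT replicate 1 and 0 elsewhere. Dlk1, a transmembrane protein of the Notch ligand family from the paternal copy, had 13 and 12 UMIs in Mat KO and 0 and 11 in WT (log2 fold change 2.005, SE 1.797, adjusted p = 0.844). Rtl1 and Dio3 had 0 UMIs in every library, which allows up to 1.58 and 1.70 CPM in Mat KO and 0.942 and 0.922 in WT.

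The labels do not say which part of the locus was deleted, and a 3' tag outside a deleted part checks nothing, so these values neither bear out nor contradict the genotype labels. The snoRNAs carry no poly(A) tail and an oligo-dT library is not built to capture them: the annotated host or snoRNA symbols AF357425 and AF357355 had 1 and 2 UMIs in all. Among the flanking genes, the chaperone gene Hsp90aa1 had 1329 and 1173 against 2153 and 2241 CPM (log2 fold change -0.78, SE 0.18, adjusted p = 0.208 by edgeR over all genes). Of the 8 locus genes tested by edgeR, none passed over all genes, and Hsp90aa1 passed when adjusted over the list alone (adjusted p = 0.00744). In lineage-low cells its log2 fold change was -0.41 (adjusted p = 0.565), and no flanking gene passed over the list alone there. Yy1, Dync1h1, Ppp2r5c, Wars and Begain did not pass, with log2 fold changes of 0.30, 0.53, -0.17, -0.91 and 0.04 in that order.

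**Figure D1:**
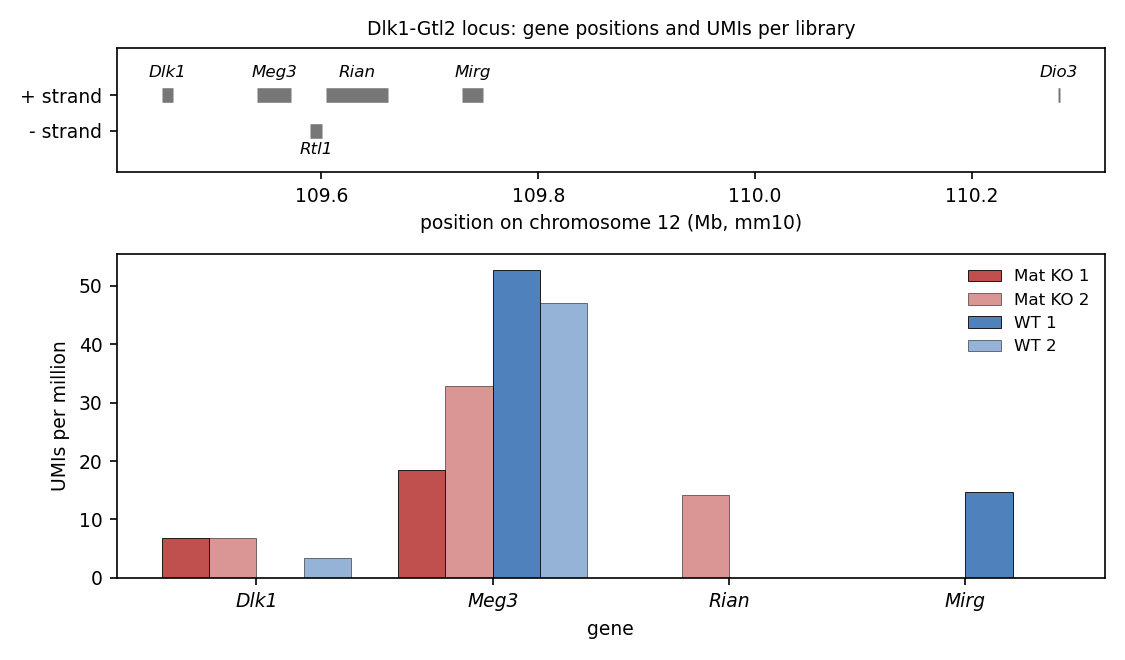
The upper panel maps the locus genes on chromosome 12 (mm10, in Mb, by strand), and the lower panel gives CPM in each of the 4 libraries (red, Mat KO; blue, WT). Meg3 stood at 18.4 and 32.8 in Mat KO against 52.8 and 47.0 in WT, while Rian and Mirg each came from 1 library.

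The second question was which genes differed over all kept cells. Of 10663 genes tested, 8 rose in Mat KO libraries and 0 fell. They were Lyz1, a lysozyme gene (log2 fold change 6.85, SE 0.71), the interferon-induced chemokine gene Cxcl10 (6.49, SE 0.57), the T cell chemokine gene Ccl5 (5.65, SE 0.80), the macrophage perforin-like gene Mpeg1 (5.23, SE 0.63), the interferon-induced gene Ifit1 (4.42, SE 0.57), the galectin gene Lgals3 (3.39, SE 0.49), the immune receptor adaptor gene Tyrobp (2.61, SE 0.28) and the monocyte surface gene Ly6c2 (2.53, SE 0.26). Adjusted p ran from 0.00174 for Cxcl10 to 0.0304 for Lgals3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A median of 95.8% of the Mat KO UMIs of these 8 genes (range 94.4% to 98.2%) lay in the 23 of 92 Mat KO cells of other lineages, which held 37.6% of all Mat KO UMIs. The leading cell of each gene and Mat KO library held a median of 87.0% of its UMIs. None passed among the 6 tested in lineage-low cells (Cxcl10 and Mpeg1 were under the expression filter) or the 7 tested with each gene's leading cell left out (all but Mpeg1), and of the 8 only Ifit1 passed after thinning. The leading WT barcodes of Cxcl10, which are those of its leading Mat KO cells, held 50% and 75% of its 4 and 8 WT UMIs. Ly6c2 and Ccl5 belong to the marker lists that define those cells, and Lyz1 and Ly6c2 have close paralogs whose reads may be shared.

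Among genes with lower values, none passed the test. The heat shock gene Hspa1a, which has the near-identical copy Hspa1b, had 4.74 and 3.39 CPM in Mat KO against 35.8 and 265 in WT (log2 fold change -5.16, adjusted p = 0.0817 by edgeR). Tex9, Tango2, Rtkn and the ribosome biogenesis gene Mphosph10 followed, with log2 fold changes of -1.95, -6.26, -3.50 and -1.57 and adjusted p from 0.208 to 0.230. In all, 834 genes had an unadjusted p under 0.05 (480 higher, 354 lower), and DESeq2 called 98 higher and 22 lower. The libraries of the genotypes did not overlap in 39.1% of genes, where chance gives 33.3%.

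**Figure D2:**
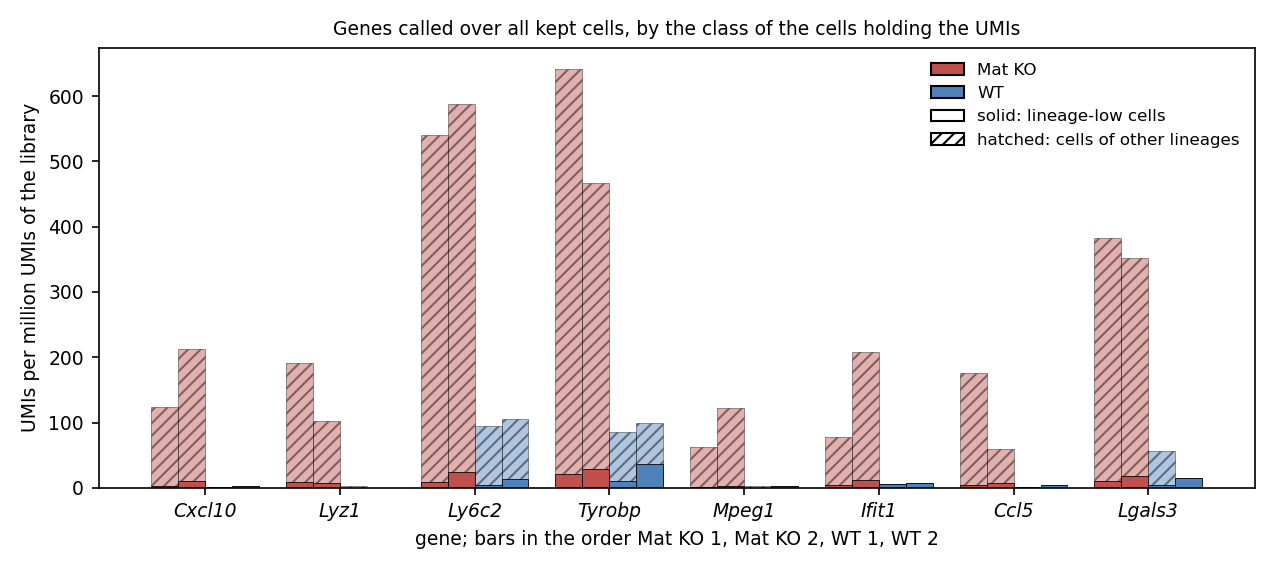
Bars give CPM of the library (vertical axis) for the 8 genes that rose in Mat KO, in the order Mat KO 1, Mat KO 2, WT 1, WT 2, with UMIs from cells of other lineages hatched and from lineage-low cells solid. Nearly the whole height of the Mat KO bars is hatched, a median of 95.8% of UMIs.

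Cells with transcripts of mature blood lineages were present in every library. Granulocyte or monocyte marker cells numbered 8 of 44 and 3 of 48 in Mat KO and 2 of 48 in each WT library, 18.2%, 6.25%, 4.17% and 4.17% of cells. B-lymphoid marker cells numbered 8, 4, 5 and 3 in the same order, and erythroid marker cells were found in WT replicate 2 alone, with 3. Together they held 45.8%, 28.7%, 16.9% and 23.6% of each library's UMIs. Granulocyte or monocyte marker cells had a median of 0.380%, 0.419%, 0.255% and 0.564% of UMIs in long-term HSC genes. B-lymphoid marker cells had 0.0589%, 0.0858%, 0.0467% and 0.361%, and lineage-low cells 0.696%, 0.582%, 0.643% and 0.572%. Some cells counted here as other lineages may thus be HSC with myeloid transcripts. The exact permutation test gave p = 0.333 for the granulocyte and monocyte share, the smallest it can give. Clustering of the 188 cells gave 4 clusters, of which 1 was B-lymphoid-like, led by Igll1, Ebf1, Vpreb3 and Vpreb1, with 6, 3, 5 and 1 cells. The largest clusters overlapped between the genotypes (exact permutation p = 0.667 each). One was led by Lcn2, Ngp and Camp, with the immediate early genes Dusp1, Jun and Fos also among its leading genes. It held 43.2% and 14.6% of Mat KO cells against 64.6% and 29.2% of WT cells. One led by Pmepa1, Epc2, Dyrk3 and Map9 held 34.1% and 72.9% against 14.6% and 43.8%. A cluster led by mitotic genes such as Kif20b, Spc24 and Cdca8, with Ifi30 and Lyz2 also among its leading genes, was left unnamed and had 4, 3, 5 and 12 cells, or 9.09%, 6.25%, 10.4% and 25.0% (exact permutation p = 0.333). At resolution 0.3 a cluster of this kind held 6.82% and 2.08% of Mat KO cells against 8.33% and 25.0% of WT cells. At resolution 1.0 a cluster led by Epc2 and Fam117b, with Map9 among its leading genes, held 13.6% and 54.2% of Mat KO cells against 6.25% and 4.17% of WT cells (exact permutation p = 0.333). At that resolution Lcn2, Ngp and Camp marked a cluster led by Retnlg, with 15.9% and 6.25% of Mat KO against 4.17% and 2.08% of WT cells. Dusp1, Jun and Fos marked another, led by Ccl4 and Gem, with 22.7% and 8.33% against 56.25% and 22.9% (exact permutation p = 0.333 each).

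Gene lists fixed beforehand were compared over all kept cells. Lists of ribosome, snoRNP and energy genes fell in Mat KO by camera at its preset correlation. For cytosolic ribosomal proteins 80 of 81 members were lower (median log2 fold change -0.27, adjusted p = 1.92e-05), with Rps26 at -0.51 and Rpl39 at -0.45. For mitochondrial ribosomal proteins 60 of 77 were lower (median -0.38, adjusted p = 1.92e-05), led by Mrpl36 at -1.61. For proteins of the snoRNPs, the particles that modify rRNA, and their assembly factors, 23 of 28 were lower (median -0.34, adjusted p = 0.00472), with Ruvbl1 at -1.13, Nhp2 at -0.91, Nop10 at -0.68 and Dkc1 at -0.89. For ribosome biogenesis 51 of 65 were lower (median -0.34, adjusted p = 0.00597), led by Mphosph10 at -1.57. For translation factors 38 of 51 were lower (median -0.22, adjusted p = 0.00991), with Gspt1 at -1.09. For nuclear genes of oxidative phosphorylation 70 of 78 were lower (median -0.35, adjusted p = 8.13e-06), led by Ndufa4 at -0.79. The proteasome list had 32 of 38 lower (median -0.17, adjusted p = 0.0477), led by Psmd7 at -0.92. No single member of these 7 lists passed the edgeR test, and none did when adjusted over the list alone. With an estimated correlation no list passed, and these 7 had adjusted p from 0.484 to 0.646, the latter for cytosolic ribosomal proteins. The estimate itself was -0.0034 for snoRNPs, below the preset value, so correlation among members does not account for that loss. With 4 libraries this repeat has little power and cannot decide whether the lists differ. At the preset correlation, calls ended without Mat KO replicate 2 for snoRNPs (adjusted p = 0.116), without Mat KO replicate 2 or WT replicate 2 for ribosome biogenesis (0.0640 and 0.401) and translation factors (0.0634 and 0.125), and without either of these or Mat KO replicate 1 for the proteasome (0.163, 0.265 and 0.0679). The proteasome call also ended with RLE factors (0.0555), the stricter gene filter (0.0670), the replicate block (0.0605) and in cells with Y-linked transcripts (0.160), the translation factor call after thinning (0.215) and in cells with Xist (0.386), and the ribosome biogenesis call in cells with Xist (0.166).

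The S phase list also fell, with 36 of 42 members lower (median -0.63, adjusted p = 8.95e-08 by camera; adjusted p = 0.484 with an estimated correlation). Its leading members were the DNA helicase subunit genes Mcm2 (-1.88) and Mcm4 (-1.13), and none of its genes passed over all genes or when adjusted over the list alone. The G2/M list did not pass (37 of 53 higher, median 0.22, adjusted p = 0.192), with Cenpf at 1.01, Gas2l3 at 1.24 and Kif20b at -1.05. Its genes held 1.17% and 0.765% of UMIs in Mat KO and 0.851% and 0.839% in WT, and the result turned on the library left out: the list rose and passed without Mat KO replicate 2 (adjusted p = 4.39e-06) and pointed down without Mat KO replicate 1 (0.0727). It also turned with the cells used, falling past the threshold in cells with Xist (1.27e-06). The erythroid list fell (9 of 9 lower, median -1.99, adjusted p = 0.000114; adjusted p = 0.514 with an estimated correlation), led by Blvrb at -1.67 and Car2 at -0.76. Its member Car1 had 1458 UMIs in WT replicate 2, the library with the erythroid cells, against 35, 0 and 18 in the others, and without that library the list did not pass (adjusted p = 0.559), nor did it after thinning (0.215), in cells with Xist (0.709) or in lineage-low cells with the limits as set (0.672) or lower (0.827); with the higher limits it fell and passed (0.0285). For this list 4 members passed when adjusted over the list alone.

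Immune and myeloid lists rose over all kept cells. The interferon response list had 26 of 41 members higher (median 0.61, adjusted p = 4.65e-07), with Cxcl10 and Ifit1 past the test and 5 members when adjusted over the list alone. Rsad2 and Ifi27l2a stood at 2.72 and 2.83 without passing. The granulocyte and monocyte list had 17 of 19 higher (median 1.69, adjusted p = 4.65e-07), with Ly6c2 past the test and 4 when adjusted over the list alone, and with Lyz2 at 2.84, Ccr2 at 3.71 and Fcnb at 4.37. The B-lymphoid list had 11 of 15 higher (median 0.60, adjusted p = 0.00296), with Blnk at 1.28, Dntt at 0.80, H2-Aa at 1.247 and Vpreb3 at 1.16. The T and NK list had 3 of 5 higher (median 0.21, adjusted p = 0.0255), with Ccl5 past the test. Each of these 4 lists had adjusted p = 0.484 with an estimated correlation. The granulocyte and monocyte list did not pass without Mat KO replicate 1 (adjusted p = 0.619), which held 8 of the 11 Mat KO cells of that class. The B-lymphoid call ended without Mat KO replicate 2 or WT replicate 2 (adjusted p = 0.0797 and 0.180) and the T and NK call without either replicate 1 (0.116 for Mat KO, 0.151 for WT), on ranks (0.459) and with each gene's leading cell left out (0.141). Thinning to equal depth ended the granulocyte and monocyte call (adjusted p = 0.554) and the B-lymphoid call (0.215) and left too few T and NK genes to test. In cells with Xist the interferon and T and NK lists did not pass (adjusted p = 0.984 each) and the B-lymphoid list fell (4.12e-27). In lineage-low cells, which are defined by 3 of these lists, the adjusted p was 0.585 for the interferon list, 0.111 for granulocytes and monocytes, 0.835 for B-lymphoid genes and 0.618 for T and NK genes. The granulocyte and monocyte list rose and passed there with the lower and the higher limits (adjusted p = 0.00317 and 1.75e-05), while the other 3 did not pass with either.

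Of the 28 lists tested over all kept cells, 13 passed, 4 higher and 9 lower. The long-term HSC list did not pass (15 of 35 higher, median -0.02, adjusted p = 0.740), with Ctnnal1 at -1.24 and Sult1a1 at 0.96, and rose past the threshold in cells with Xist alone (adjusted p = 0.00714). The share of UMIs in these HSC genes had a median over cells of 0.584% and 0.543% in Mat KO and 0.594% and 0.547% in WT. PI3K-mTOR genes (median 0.12, adjusted p = 0.348) and quiescence regulators (0.08, adjusted p = 0.808) did not pass. Their leading members were Inpp5d (0.73), Rptor (1.41) and Ddit4 (1.35), and Btg1 (0.70), Cdkn2c (1.58) and Rbl1 (-0.77). The 11 other lists that did not pass were multipotent progenitor genes (adjusted p = 0.0732), other imprinted genes (0.0911, with 16 of 21 lower), mast cells and basophils (0.100), immediate early and stress genes (0.234), tRNA synthetases (0.246), p53 targets (0.503), glycolysis (0.504), the locus flank (0.582, with 0.0234 by fry's mixed test, which counts changes in both directions), the unfolded protein response (0.740), megakaryocytes (0.842) and stroma (0.941). Some of these passed elsewhere: multipotent progenitor genes rose and tRNA synthetases fell without WT replicate 1 (0.0182 and 0.0112), mast cell and basophil genes rose without WT replicate 2 (0.0152), and multipotent progenitor genes rose with each gene's leading cell left out (0.00877). In cells with Y-linked transcripts quiescence regulators and multipotent progenitor genes rose (0.0311 and 0.0252) and other imprinted genes fell (0.0118). All these calls are at the preset correlation, at which swapped library labels passed up to 7 lists. With an estimated correlation, run over all kept cells and not in these settings, adjusted p was 0.484 for multipotent progenitor and other imprinted genes, 0.711 for tRNA synthetases, 0.566 for mast cells and basophils, 0.883 for quiescence regulators and 0.935 for long-term HSC genes.

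Lineage-low cells, a set chosen after the data were seen, numbered 28 and 41 in Mat KO and 41 and 40 in WT. In them 5 of 9980 genes rose in Mat KO and 0 fell by edgeR, while DESeq2 called 39 higher and 11 lower. Counts assigned to Rn45s, the entry for the 45S precursor of ribosomal RNA, rose by a log2 fold change of 0.98 (SE 0.09, adjusted p = 0.000513 by edgeR). They went from 43581 and 52104 CPM in WT to 80162 and 101386 in Mat KO. The other genes called by edgeR were the microtubule-associated gene Map9 (1.72, SE 0.25, adjusted p = 0.0348), Neurl3 (1.63, SE 0.26), the zinc-finger transcription factor gene Klf6 (1.29, SE 0.20) and Ccdc122 (3.59, SE 0.57), the last 3 each at adjusted p = 0.0407. Klf6 belongs to the list of immediate early and stress genes, which respond to cell handling. Over all kept cells none of the 5 passed, with Rn45s at 0.75 (adjusted p = 0.0759). With lower limits, which leave out 3 more cells, Rn45s alone passed (0.93) and the other 4 had adjusted p from 0.0594 to 0.0906 with log2 fold changes of 1.60 for Map9, 1.53 for Neurl3, 1.38 for Klf6 and 3.78 for Ccdc122. With higher limits all but Neurl3 (1.484, adjusted p = 0.0540) passed, Rn45s at 0.86. Over all kept cells of known sex class, the genotype difference of Rn45s was lower in cells with Y-linked transcripts than in cells with Xist, by 0.53 on the log2 scale (adjusted p = 6.77e-11, edgeR interaction test). Those cells include B-lymphoid marker cells, of which 9 of 12 in Mat KO had Y-linked transcripts and 0 had Xist, against 2 and 4 of 8 in WT. Cell make-up is thus not separated from sex, and no such test was run on lineage-low cells. Rn45s is a multi-copy sequence with no poly(A) tail, so its counts are uncertain. They may not separate the precursor from the mature ribosomal RNA cut from it.

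Against the spike-ins, Rn45s gave 0.0622 and 0.0783 UMIs per spike-in UMI in Mat KO and 0.0525 and 0.0689 in WT over all kept cells, which overlap (exact permutation p = 0.667). All other mouse transcripts gave a median over cells of 0.606 and 0.634 UMIs per spike-in UMI in Mat KO and 0.833 and 0.965 in WT (0.620 ± 0.0204 against 0.899 ± 0.0935, SD, n = 2 libraries each; exact permutation p = 0.333). Rn45s made up 8.13% and 10.3% of a cell's UMIs in Mat KO and 5.44% and 6.61% in WT, by median.

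**Figure D3:**
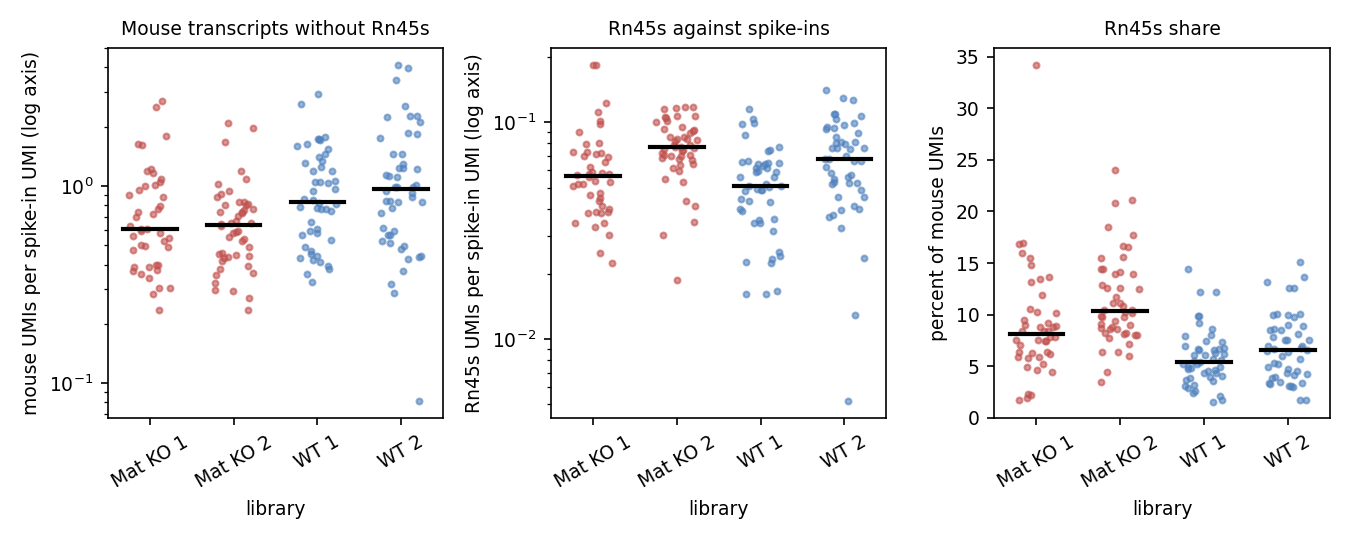
Each point is a kept cell and each line the library's median: mouse UMIs without Rn45s per spike-in UMI (left, log axis), Rn45s UMIs per spike-in UMI (middle, log axis) and Rn45s as a percent of mouse UMIs (right). Median lines of the genotypes do not overlap on the left (0.606 and 0.634 against 0.833 and 0.965) or on the right, and overlap in the middle.

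In lineage-low cells with the limits as set 6 of 27 lists fell and 0 rose by camera, whereas the granulocyte and monocyte list rose with both other sets of limits. The G2/M list had 47 of 50 members lower (median -0.86, adjusted p = 1.94e-12; adjusted p = 0.773 with an estimated correlation), led by the topoisomerase gene Top2a (-1.41), Ckap2l (-3.13), Cks1b (-1.57) and Hmgb2 (-0.66). With the higher limits the list passed at a median of -0.43 (adjusted p = 2.28e-05 by camera). With the lower limits the call ended (median -0.14, adjusted p = 0.114): 1 WT replicate 1 cell that they leave out held 9025 of the 17105 G2/M UMIs of that library's lineage-low cells. The median was -1.41 without Mat KO replicate 1 and -0.57 without Mat KO replicate 2, and the list passed without each library in turn. The S phase list had 36 of 42 lower (median -0.80, adjusted p = 8.40e-08; adjusted p = 0.818 with an estimated correlation), with Mcm2 at -1.91, Fen1 at -2.29, Cdca7 at -0.95 and Mcm6 at -0.95. Without WT replicate 2 it did not pass (median -0.40, adjusted p = 0.197). No member of the S phase list passed when adjusted over the list alone, against 4 of the G2/M list. The share of lineage-low cells with at least 2 G2/M genes at equal depth was 88.5% and 85.7% in Mat KO and 94.9% and 91.7% in WT (exact permutation p = 0.333), close to the highest value it can take; without thinning it was 96.4% and 100% against 100% and 100%, which overlap.

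Nuclear genes of oxidative phosphorylation fell in lineage-low cells, with 72 of 78 lower (median -0.39, adjusted p = 2.26e-09; adjusted p = 0.602 with an estimated correlation), including Ndufa4 (-0.90), Atp5j2 (-0.94), Uqcrq (-1.10) and Ndufs8 (-1.14). This list passed at the preset correlation without each library in turn and with both other sets of limits. Mitochondrial ribosomal proteins (56 of 76 lower, median -0.36, adjusted p = 0.00103), the proteasome (33 of 38, median -0.29, adjusted p = 0.00926) and cytosolic ribosomal proteins (71 of 80, median -0.13, adjusted p = 0.0163) fell as well, with adjusted p = 0.602, 0.602 and 0.818 with an estimated correlation. Leading members were Mrpl43 (-2.02), Psma2 (-0.98) and Rpl39 (-0.38). Calls ended for mitochondrial ribosomal proteins without Mat KO replicate 1 (adjusted p = 0.0847), for the proteasome without Mat KO replicates 1 or 2 or WT replicate 2 (0.0672, 0.106 and 0.100, the last with a median of -0.19) or with the higher limits (0.0798), and for cytosolic ribosomal proteins without Mat KO replicate 1 or WT replicates 1 or 2 (0.533 with a median of -0.08, 0.0944 and 0.113). The snoRNP list did not pass (21 of 28 lower, median -0.33, adjusted p = 0.111), nor did ribosome biogenesis (-0.10, adjusted p = 0.782), translation factors (-0.09, adjusted p = 0.618) or long-term HSC genes (23 of 34 higher, median 0.26, adjusted p = 0.111).

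**Figure D4:**
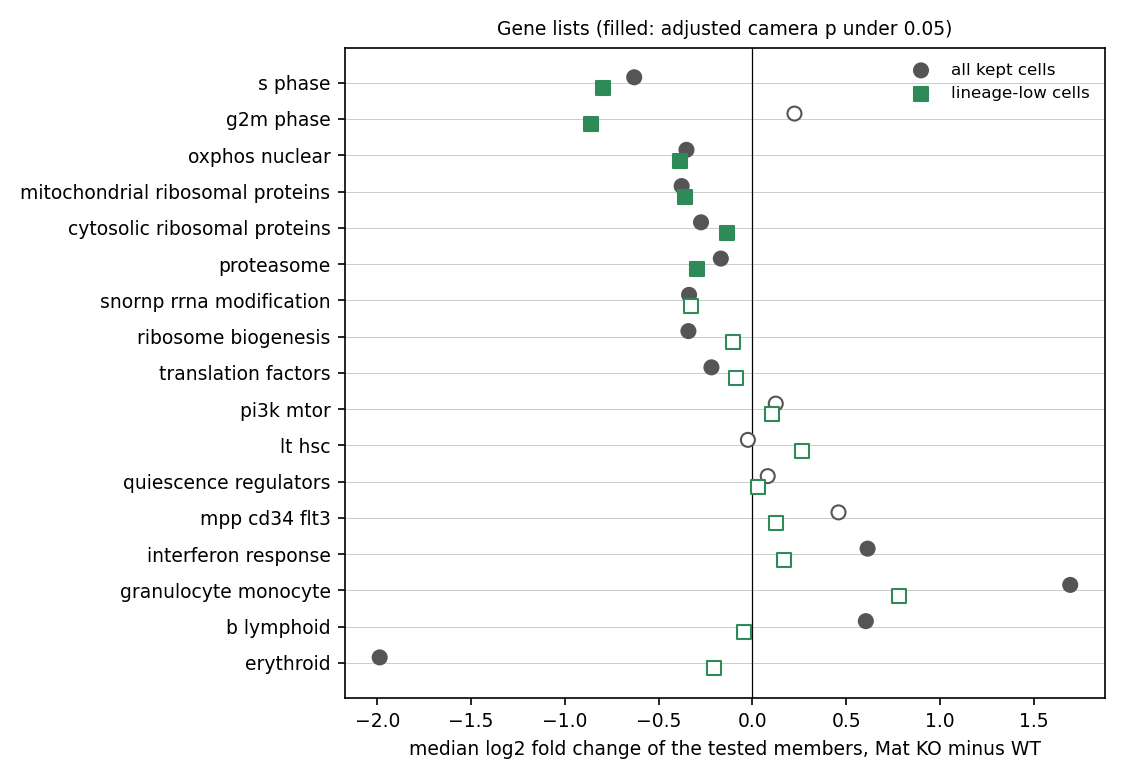
Each point is the median log2 fold change (Mat KO minus WT, horizontal axis) of a list's tested members over all kept cells (circles) and in lineage-low cells (squares), filled where camera's adjusted p at the preset correlation was under 0.05. The G2/M list goes from 0.22 to -0.86 between the cell sets, and to -0.14 in lineage-low cells with lower limits, which is not drawn.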

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

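Apart from the thinning of all kept cells, a setting fixed beforehand, the result here and all tests weighed in this part were chosen after the data were seen or run on lineage-low cells, a set chosen then. For the thinning, the left-out leading cell and the share of cells tested on the S phase and G2/M lists, the expected outcome was written before that test's own result was seen.

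The difference between Mat KO and WT itself differed between cells with Y-linked transcripts and cells with Xist for 50 of 10189 genes (edgeR's quasi-likelihood test of the interaction with library as a block, Benjamini-Hochberg adjustment), which is what brought it up. Of these genes 42 had the higher difference in cells with Y-linked transcripts, and 10 are B-lymphoid markers, led by Igll1 (7.64 on the log2 scale), Vpreb3 (7.68) and Vpreb1 (7.56). They also include Rn45s (-0.53, adjusted p = 6.77e-11) and, of the 8 genes called over all kept cells, Ifit1 (8.11), Cxcl10 (5.98) and Ccl5 (6.46). Among B-lymphoid marker cells, 9 of 12 in Mat KO had Y-linked transcripts and 0 had Xist, against 2 and 4 of 8 in WT. Sexes were read from the cells and not from the labels, and both sexes of a library share its preparation. In the interaction test 523 of the 10189 genes had an unadjusted p under 0.05, close to the share that chance gives. Its sums held 11 to 23 cells each, so a few B-lymphoid marker cells can weigh heavily in them. The test did not separate sex from cell make-up.

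The 8 genes higher in the Mat KO sums over all kept cells were weighed against depth and cell make-up. Lower depth per cell in Mat KO as the whole cause is argued against by the thinned cells, in which their median log2 fold change was 4.09 (0.63 for Ly6c2 to 7.78 for Lyz1) against 4.82 (2.52 to 6.83) before, although with fewer UMIs only Ifit1 passed. The ranges in this paragraph come from a separate estimate that also covers genes under the expression filter. They differ slightly from the fold changes of the test. A few cells of other blood lineages, which a sort for HSC should remove, remain a candidate explanation, since a median of 95.8% of the Mat KO UMIs lay in such cells and the abundant myeloid transcript Lyz2 stood at 3549 and 3055 CPM in Mat KO against 754 and 189 in WT, although the whole granulocyte and monocyte list held 3.42% and 0.606% of UMIs against 0.702% and 0.373%, which overlap. Whether lineage-low cells changed as well cannot be told apart, because their median was 1.04 with a range over the 8 genes of 0.42 to 5.72. That median alone lay below the limit written down for arguing against such a change. A requirement on the range was added after the value was seen. The leading cell of Lyz1, Ly6c2, Tyrobp, Mpeg1 and Lgals3 had 0.354% of its UMIs in long-term HSC genes in Mat KO replicate 1. In Mat KO replicate 2 it had 0.597%, against a median of 0.582% in that library's lineage-low cells. Whether such cells are of another lineage or HSC with myeloid transcripts was not tested. Genotype could still change how many such cells the sort admits, which was not tested beyond the shares per library.

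The higher share of Rn45s in Mat KO was weighed against cell make-up and total RNA content. Cells of other lineages are argued against, since in lineage-low cells the log2 fold change was 0.98, no lower than over all kept cells. Fewer other transcripts per spike-in UMI in Mat KO stay a candidate explanation: Rn45s per spike-in UMI differed by a ratio of 1.16 over all kept cells and 1.22 in lineage-low cells, with overlapping libraries in both. On that reading the rise in share may not be a rise of Rn45s per cell, and the cause of the lower content of other transcripts, technical or biological, stays open. Between same-numbered libraries, which the labels do not pair, Rn45s per spike-in UMI was higher in Mat KO each time. Over all kept cells it was 0.0622 against 0.0525 in replicates 1 and 0.0783 against 0.0689 in replicates 2. A rise per cell is therefore not excluded.

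The lower S phase and G2/M lists in Mat KO lineage-low cells were weighed against depth and single cells. Lower depth is argued against by a G2/M median of -0.54 after thinning, and leaving out each gene's leading cell in every library gave -0.71. A few dividing cells near the lineage limits remain a candidate explanation for the G2/M list, whose median was -0.14 with the lower limits, but not for the S phase list, at -0.85, whose call ended without WT replicate 2 (adjusted p = 0.197). Genotype cannot be told apart from chance here, since the share of cells with G2/M genes differed by -6.18 percentage points between 2 libraries and 2, on a measure close to its upper limit.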

How the results depend on the processing

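The lineage-low sets, the left-out leading cells, the sex-specific sets and the counts without Rn45s were chosen after the data were seen; the other settings were planned. The count of genes that differed was 8 with TMM, and was within 1.5-fold of it with RLE factors, totals alone, the stricter filter, all barcodes, no high-UMI cells (which removed no cell), cells with Xist and no Rn45s. It was 149 without a filter, 120 with DESeq2, 5 with at least 2000 genes per cell, 1 with thinned cells, 109 with the replicate block, 5, 1 and 24 in lineage-low cells with the limits as set, lower and higher, 0 with each gene's leading cell left out, 1 in cells with Y-linked transcripts, and 17 to 123 with 1 library left out (17 without WT replicate 2, 34 without WT replicate 1, 69 without Mat KO replicate 1, 123 without Mat KO replicate 2), where the lone library of an arm is assumed to vary like the other group. All 8 genes were kept in each of these 4 fits, with the block and with DESeq2, and none of the 6 tested in lineage-low cells as set. In cells with Xist only the count was similar, which does not mean that the same genes were called. Ifit1 changed sign there, and 0 of 12 B-lymphoid and 1 of 11 granulocyte and monocyte marker cells of Mat KO had Xist. The count of locus genes was 0, and was 1 (Hsp90aa1) without a filter, with DESeq2, with the block and without either Mat KO replicate, so 0 to 1 over the left-out libraries. The 13 gene lists became 8 with thinned cells, 6, 6 and 7 in lineage-low cells with the limits as set, lower and higher (the last 2 with the granulocyte and monocyte list rising), 0 with an estimated correlation and 0 with fry, whose mixed test passed 1, the locus flank. Non-overlapping clusters numbered 1, against 5 at resolution 1.0 and 0 with at least 2000 genes per cell. The cause of these moves was not tested beyond the weighing above. Over genes, same-numbered libraries did not deviate together (correlation -0.017), which does not settle whether they share a batch. The labels state no pairing. In both genotypes the cluster led by Lcn2 was larger in replicate 1 (43.2% against 14.6% in Mat KO, 64.6% against 29.2% in WT). That led by Pmepa1 was larger in replicate 2 (72.9% against 34.1%, 43.8% against 14.6%). The B-lymphoid-like cluster was larger in replicate 1, and the mitotic one had no shared direction.

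Log2 fold changes that changed sign, among 78 named genes over 19 settings, were as follows, and the cause was not tested. Thinned cells gave Nkg7 -0.52, and the replicate block gave Begain -0.79. Leaving out 1 library gave Begain -6.43 to 2.04, Nkg7 -0.55 to 1.83, Ppp2r5c -0.37 to 0.047 and Car1 -12.27 to 0.71. Lineage-low cells gave Begain -0.47, Car1 0.57, Blnk -0.40, Dntt -0.045, H2-Aa -1.63, Lck -1.51, Nkg7 -0.98 and Cenpf -0.64. Without each gene's leading cell, H2-Aa was -0.48 and Nkg7 -0.18. In cells with Xist, Ifit1 was -0.43, Psmc6 0.14, Rsad2 -0.23, Car2 0.12, Blnk -4.62, Dntt -4.20, H2-Aa -1.01, Vpreb3 -3.67, Lck -1.003 and Gas2l3 -0.57. Of the other gene values, 1302 kept their direction and side of the threshold, 64 passed it and 34 lost it.

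In lineage-low cells the 5 genes that rose were kept without each library in turn, in fits that called 24 to 69 genes. The libraries allow 3 splits, including the real one, too few for a share under 0.05. Over all kept cells the swapped splits gave 0 genes and at most 7 lists, against 8 and 13. In lineage-low cells they gave 0 genes and at most 3 lists, against 5 and 6. Each swapped group mixes Mat KO and WT, and common dispersion over all kept cells was 0.293 and 0.299 against 0.255 in the real split. That makes calls harder, so 0 genes there says little about the real calls. The planned setting without cells that hold at least 3 markers of another lineage was not run, since nearly every cell holds them and it leaves 0, 1, 2 and 1 cells. Low coverage limits the locus genes, since Rian and Mirg, seen in 1 and 3 cells, stood under the expression filter. Median UMIs per cell were in a Mat KO to WT ratio of 0.588, but whether depth set the Rian and Mirg counts was not tested.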

Other observations

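The tests in this part were chosen after the data were seen, apart from the gene lists. Handling and stress genes did not move together in lineage-low cells. Of 22 immediate early and stress genes 13 were higher in Mat KO (median 0.07, adjusted p = 0.585 by camera), with Klf6 past edgeR's test over all genes and 6 members when adjusted over the list alone. The heat shock gene Hspa1a had 9 and 5 UMIs in Mat KO and 113 and 511 in WT (log2 fold change -4.25, adjusted p = 0.141). At clustering resolution 1.0, a cluster led by Jchain, Txndc5, Hspa1a, Hspa1b and Slpi had 13 of 48 cells in WT replicate 2, 2 in Mat KO replicate 1 and 0 in the other libraries. Only 8 cells of WT replicate 2 were left out as other lineages, so its lineage-low cells include some of these 13. Jchain and Txndc5 are in none of the lists that set the lineage limits. The neuropeptide gene Gal had 0 UMIs in both Mat KO libraries and 263 and 19 in WT. The centromere cohesion gene Sgol2a had 5 and 1 against 204 and 85, without passing (adjusted p = 0.308 by edgeR).

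Nutrient signalling and stem cell genes in lineage-low cells did not pass as lists. The PI3K-mTOR list had 22 of 39 members higher (median 0.11, adjusted p = 0.685 by camera), led by Rragb (3.26), Ddit4 (1.45) and Rptor (1.68), and the quiescence list had 13 of 26 higher (adjusted p = 0.827), with the Notch target gene Hes1 at 0.33 and the cyclin kinase inhibitor gene Cdkn1a at 0.50. Akap13 stood at 1.01 (adjusted p = 0.112). The HSC genes Sult1a1, Clec1a and Ctnnal1 stood at 1.26, 1.65 and -1.26.

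Spike-in UMIs of a barcode were correlated between libraries across the 48 barcodes (Spearman's rho 0.823 to 0.940, barcodes not being independent replicates). Among the 44 barcodes with a kept cell in every library, the mean of mouse UMIs per spike-in UMI was lower in Mat KO than in WT in 33. For genes with at least 200 UMIs and 80% of a library's UMIs in 1 cell, 55 of 84 pairs with another library had a UMI at the same barcode there, against 28.9 from the rate at other barcodes. That rate takes no account of the shared yield of a barcode, so the excess may arise without UMIs passing between libraries. For Cxcl10, whose leading Mat KO cells had barcodes 22 and 47, the leading barcode was 47 with 50% of 4 UMIs in WT replicate 1 and 22 with 75% of 8 UMIs in WT replicate 2, so WT counts this low may not be independent of the Mat KO libraries. The barcodes without a cell had a median of 11 and 12 UMIs in Mat KO and 21 and 21 in WT. A barcode of Mat KO replicate 1 that was not kept, with 717 genes, had 74.9% of its UMIs in Rn45s.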
